A study of Danio rerio with 9 samples.

How the data were processed

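The data are single-cell RNA sequencing libraries of whole zebrafish hearts carrying a myl7:EGFP transgene, which marks cardiac muscle, at 9 stages from 25 hours to 60 days after fertilization. Each stage had 1 library, so 9 libraries entered the work and no stage had a replicate. Per the labels' protocols, dead cells were depleted with a levitation device, each sample ran on its own lane, and libraries were made with 10x Genomics 3' chemistry, which reads transcript ends and tags each molecule with a unique molecular identifier (UMI). Per the submitters' processing notes, STARsolo, Scanpy and the danRer11 genome build were used; their versions and the role of Scanpy are not given in the sources used here. The deposited matrices hold raw UMI counts per gene and cell, whole numbers that were not normalized. The deposited barcodes were already limited to called cells. The lowest UMI total of a barcode was 500 at 25 hpf and between 4864 and 7787 in the other libraries, so the 25 hpf library was held to a lower limit.

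All files listed 32057 genes. The 25 hpf file carried other symbols for 295 of these, so genes were joined by Ensembl identifier and named by the symbols of the other files. Where 1 symbol belongs to several identifiers, the genes were kept apart. Hemoglobin genes, mitochondrially encoded genes and others with near-identical copies are uncertain, because the counting could split their reads.

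Cells with at least 200 genes and at most 30% mitochondrial UMIs were kept. Doublets were called per library with Scrublet as run by scanpy 1.11.5, at an expected rate of 0.8% per 1000 cells, and removed. The caller marked between 0.132% and 5.33% of the cells of a library. Cells of all libraries were clustered together on 2000 variable genes, 40 principal components and 20 neighbours, with Leiden clustering (igraph 0.11.9) at a resolution of 1.5. A cluster was named from marker genes fixed before the data were examined. It needed at least 3 detected markers and no more markers of another class than of its own among its top 10 genes. Clusters that missed these conditions stayed unnamed, as would clusters of low UMI counts with none of their markers among the top genes. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and matplotlib 3.10.9 for figures. No batch correction was applied, and with 1 library per stage a library and a stage cannot be told apart. The first naming compared each cluster with all others; after it had been seen, and before any test was run, it was replaced by 2 passes, in the second of which clusters of the same class were left out of the comparison. A cluster whose class differed between the passes stayed unnamed.

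UMI counts were summed per library over all cardiomyocyte-like cells and over all endothelial-like cells. Each sum was tested for a straight-line trend on log2 age in hours with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with TMM normalization and genes with at least 10 counts in at least 3 libraries. The departures of the libraries from the line are the error of this test. A slope is the log2 change per doubling of age. Per the series description, the number of hearts in a library depended on the stage, and it is not given. P-values measure the spread of single libraries around the line. Stages were not tested against each other.

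Cardiomyocyte-like cells were split into atrial and ventricular by myh6 and myh7, the atrial and ventricular heavy chains, alone. Cells with a myh6 share of at least 0.8 of the UMIs of both genes were called atrial and those with at most 0.2 ventricular, with at least 5 UMIs of both. The chambers were compared within libraries with the library as a block, and the interaction of chamber with log2 age was tested in the same way. Neither gene was reported or counted in a list in these tests.

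Gene lists and markers of other cell classes were fixed before the data were examined; running them on the chamber tests was added later. They were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, and again with an estimated correlation. P-values were adjusted by Benjamini and Hochberg over genes or over lists. Shares of cells have exact binomial (Clopper-Pearson) 95% intervals, and a share of 0 has the upper limit of 3 counts. Intervals and limits cover counting error only. Trends of shares, of the adult globin share and of proliferation transcripts used exact two-sided permutation tests over all orders of the 9 libraries.

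Named genes followed a rule fixed before the data were examined. It took the 8 called genes per direction with the largest slope or difference among those with a mean of at least 20 CPM (counts scaled to the total of a sum), up to 4 members of each described list with the smallest adjusted p, and a fixed set of heart genes. Ribosomal, mitochondrially encoded and clone-named genes were left out of the first part. Alternatives covered DESeq2 1.42.0, other size factors, no low-count filter, thinned sums, a stricter cell filter, doublets kept, clustering within each library, stage rank in place of age, other chamber limits, each library left out, and the 25 and 48 hpf libraries left out together. A common minimum of UMIs for all libraries was added after the data were seen. Each test across genes was also run on 40 orders of the ages, or flips of the chambers within libraries, the real one included.

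The tests were tried on simulated counts with 100 genes changed at each size. In both trends and the chamber by age test the size was a slope per doubling of age. In the chamber difference it was the difference between the chambers. A slope adds up over all doublings between the first and last stage, so equal sizes are not equal changes. The percentages therefore do not rank the chamber difference against the other tests. A size of 1 log2 unit was recovered for 100% of the changed genes in the cardiomyocyte trend and 100% in the endothelial trend. It was recovered for 73% in the chamber difference and 99% in the chamber by age test. A size of 0.5 log2 units was recovered for 58%, 64%, 11% and 67%. False genes made up 3.1%, 4.1%, 9.7% and 2.4% of the calls, so the chamber difference exceeded the aimed rate of 0.05 in the simulation.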

Results

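Whole hearts were profiled cell by cell through zebrafish development, and the series asks how the cells of the heart change from the embryonic tube to the young adult. The stages were 25, 36 and 48 hours post fertilization (hpf) and 5, 7, 14, 21, 30 and 60 days post fertilization (dpf), with 1 library each and no replicates. The libraries held between 1072 barcodes at 7 dpf and 8342 at 21 dpf, and total counts between 23069552 UMIs at 30 dpf and 121330604 at 21 dpf. The median per barcode was lowest at 25 hpf, with 6169 UMIs, and highest at 7 dpf, with 23794 UMIs.

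Cardiomyocyte-like cells made up 34.5% of kept cells at 25 hpf (95% interval 33.2 to 35.8), 16.3% at 48 hpf, 51.5% at 21 dpf and 33.0% at 60 dpf. Endothelial-like cells, which take in endocardium and vessels, ranged from 18.8% at 60 dpf to 39.0% at 7 dpf. Epicardial-like cells, of the outer layer of the heart, were 0 of 5381 cells at 25 hpf and 15.3% (14.3 to 16.4) at 14 dpf. The counting limit of 0.0558% at 25 hpf applies to clusters named so and does not bound the true share, since 35.6% of the cells there were unnamed. Unnamed cluster 26, with 199 cells at 25 hpf and 359 at 36 hpf, met 11 fibroblast markers and 3 epicardial markers and had jam2b among its leading genes. Mural or smooth muscle-like cells were also absent from the clusters of the first 3 stages. They made up 12.5% at 5 dpf, 8.96% at 7 dpf, 10.3% at 14 dpf and 5.51% at 21 dpf. Later they made up 19.5% at 30 dpf and 35.8% (34.3 to 37.3) at 60 dpf. Fibroblast-like cells were 0.378% at 14 dpf, 2.78% at 21 dpf, 4.97% at 30 dpf and 4.11% at 60 dpf. These late shares depend on the clustering. The fibroblast-like cluster held 454 cells here, 47.4% of them from 21 dpf. With doublet calls kept it held 466 cells, 82.8% of them from 60 dpf.

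**Figure D1:**
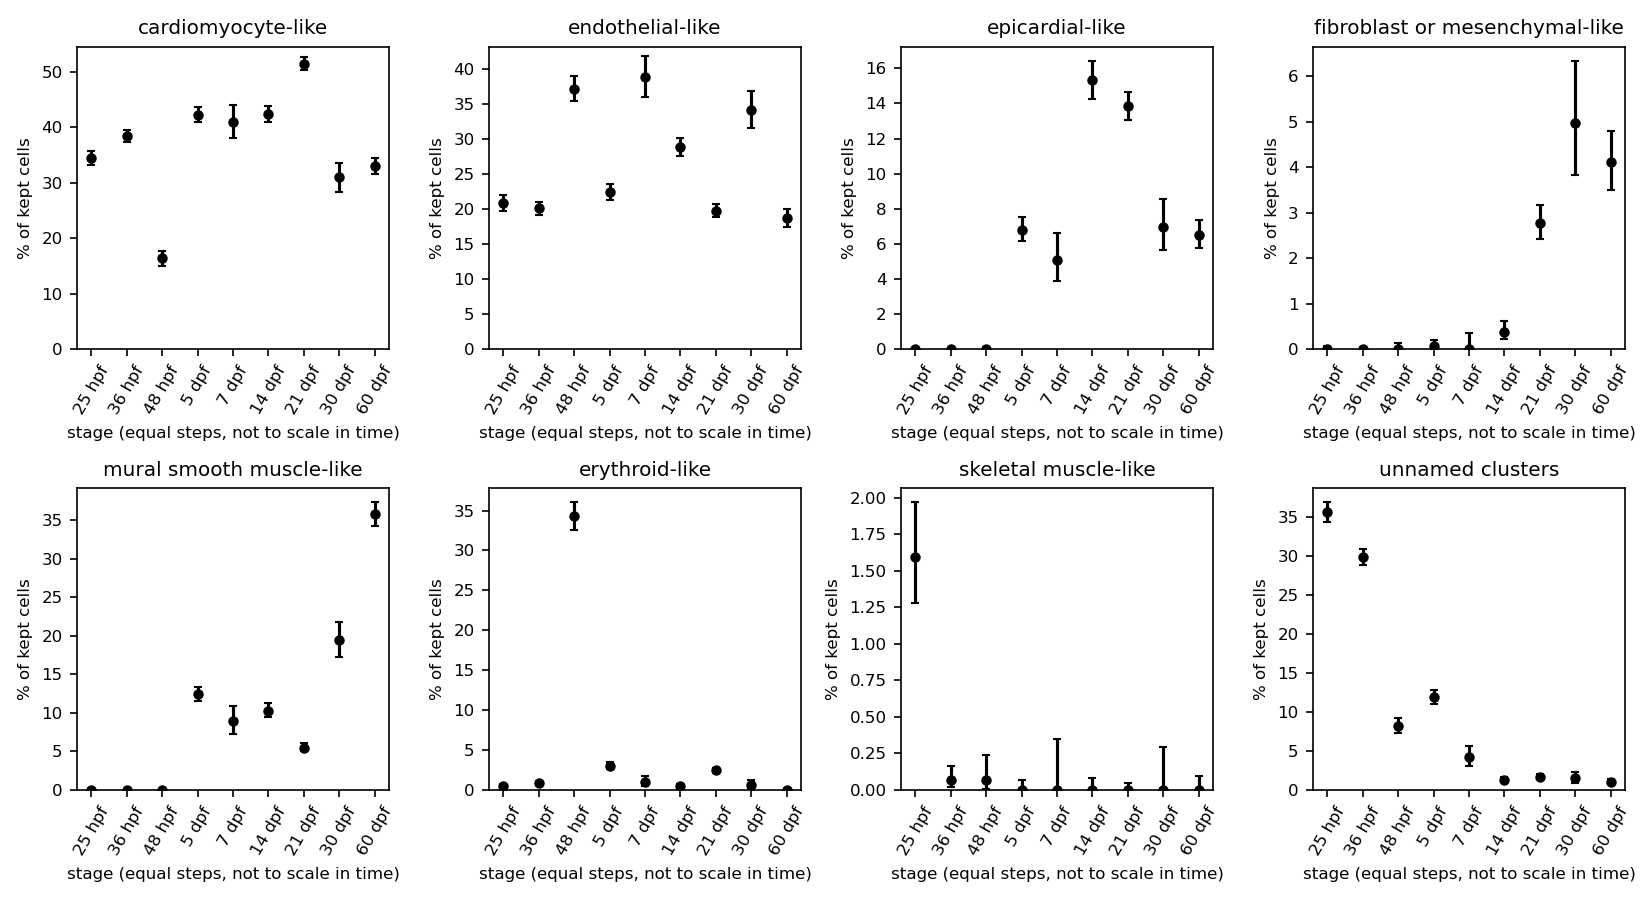
Share of kept cells (percent, vertical axis) by stage (horizontal axis, equal steps) for 7 named classes and the unnamed clusters; points are single libraries and bars exact binomial intervals of counting error. Mural or smooth muscle-like cells reached 35.8% at 60 dpf, and erythroid-like cells stood at 34.3% at 48 hpf.

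Of 12 classes tested against log2 age, 3 passed by rho. Fibroblast-like cells rose (rho = 0.896, r = 0.823, adjusted p of rho = 0.0238, exact permutation test), mural or smooth muscle-like cells rose (rho = 0.831, r = 0.838, adjusted p = 0.0368, exact permutation test), and skeletal muscle-like cells fell (rho = -0.842, r = -0.552, adjusted p = 0.0238, exact permutation test). By r, fibroblast-like (adjusted p = 0.0344, exact permutation test) and mural or smooth muscle-like cells (adjusted p = 0.0196, exact permutation test) passed and skeletal muscle-like cells did not (adjusted p = 0.119, exact permutation test). Neutrophil-like cells passed by r (r = -0.796, adjusted p = 0.0344, exact permutation test) and not by rho (rho = -0.548, adjusted p = 0.196, exact permutation test). Raw exact permutation p-values of rho for the 3 classes were 0.00238, 0.00919 and 0.00397. Without the 2 libraries farthest from the median age, r was 0.773, 0.760 and -0.846. Skeletal muscle-like cells were 86 cells at 25 hpf, 5 at 36 hpf and 2 at 48 hpf. The rise of fibroblast-like cells depends on the naming, as their count was 0 at 25, 36 and 48 hpf. Unnamed cluster 26, which met 11 fibroblast markers, had 199, 359 and 57 cells at these stages. The trend was not tested with that cluster counted as fibroblast-like. The shares of cardiomyocyte-like cells (rho = 0.067, exact permutation p = 0.88) and endothelial-like cells (rho = -0.183, exact permutation p = 0.644) showed no trend. The epicardial-like share missed the threshold (rho = 0.712, adjusted p = 0.0966, exact permutation test). The number of passing classes was 0 when cells were clustered within each library, and also 0 without the 25 hpf, 36 hpf, 48 hpf or 14 dpf library. The 25 hpf library had a lower UMI limit than the others, and the mural class came mostly from cluster 1 through 21 dpf and from cluster 5 at 30 and 60 dpf.

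Unnamed clusters held 35.6% of the cells at 25 hpf, 29.9% at 36 hpf, 11.9% at 5 dpf and 1.08% at 60 dpf. Erythroid-like cells, the red blood cells, were 34.3% (32.6 to 36.0) at 48 hpf and at most 3.05% at any other stage. Hemoglobin transcripts took 29.3% of all UMIs at 48 hpf and 0.0173% at 60 dpf.

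In cardiomyocyte-like cells, genes of oxidative metabolism rose with age. Myoglobin (mb), the oxygen store of muscle, went from 11.4 CPM at 25 hpf to 17720 CPM at 60 dpf, a slope of 1.98 ± 0.18 (SE, 9 libraries) per doubling of age (edgeR adjusted p = 9.12e-05). The mitochondrial creatine kinase ckmt2a rose by 2.61 ± 0.20, the cytochrome c oxidase subunits cox6a2 and cox5b2 by 2.19 ± 0.59 and 2.13 ± 0.33, and the small heat shock protein hspb6 by 2.04 ± 0.38. The troponin I gene tnni4a went from 3.86 CPM to 2375 CPM (1.43 ± 0.34), and atp2a2a, the calcium pump of the sarcoplasmic reticulum, rose by 0.47 ± 0.09. The skeletal-type troponin genes tnni2a.4 (-4.58 ± 0.36) and tnnc2 (-2.45 ± 0.19) fell, as did lft2 (-2.97 ± 0.39), a Nodal antagonist, ppp1r3b (-1.99 ± 0.22), myl10 (-1.93 ± 0.28) and col15a1b (-1.91 ± 0.33).

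By list, 79 of 101 nuclear genes of oxidative phosphorylation rose and 0 fell (88 rose when adjusted over the list alone; camera adjusted p = 1.18e-23, adjusted p = 0.348 with an estimated correlation). Of 30 genes of fatty acid oxidation, 18 rose and 1 fell (25 and 1 adjusted over the list alone; camera adjusted p = 1.72e-08, adjusted p = 0.307 with an estimated correlation), among them acadvl (0.60 ± 0.08) and acadm (0.56 ± 0.09), dehydrogenases of this pathway. Of 23 genes of the citric acid cycle, 14 rose (20 adjusted over the list alone; camera adjusted p = 7.66e-08, adjusted p = 0.348 with an estimated correlation), with citrate synthase (cs) at 0.48 ± 0.09. Of 28 glycolysis genes, 11 rose (15 adjusted over the list alone; camera adjusted p = 2.09e-06, adjusted p = 0.307 with an estimated correlation). The mean levels of these lists, in log2 units from the mean over libraries, were highest at 30 dpf and lower at 60 dpf. They were 0.658 and 0.356 for oxidative phosphorylation and 0.573 and 0.245 for fatty acid oxidation. The citric acid cycle stood at 0.725 and 0.162, and glycolysis at 0.634 and 0.313. These levels are CPM without TMM scaling, and the mitochondrially encoded list stood at 0.57 at 30 dpf and 1.851 at 60 dpf. The stricter cell filter, with its lower mitochondrial limit, kept 454 of 1251 cardiomyocyte-like cells at 60 dpf. Whether the mitochondrial share lowered the other lists there was not tested. All 13 mitochondrially encoded genes rose (camera adjusted p = 9.22e-09, adjusted p = 0.348 with an estimated correlation), and these are uncertain. Genes of antigen presentation and interferon response rose in 12 of 17 cases, the same number adjusted over the list alone, including the invariant chain genes cd74a (1.71 ± 0.21) and cd74b (0.98 ± 0.17). Its camera call held with an estimated correlation (camera adjusted p = 1.96e-07, adjusted p = 0.0215 with an estimated correlation), but these levels were low, with a mean of 0.475 CPM for cd74a. Both cd74a and cd74b were also among the leading genes of macrophage-like cluster 39, and cd74a was 1 of the macrophage markers. Macrophage RNA was not tested as a source of their rise.

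Of 14 pacemaker and atrioventricular canal genes, 9 fell and 1 rose (9 and 2 adjusted over the list alone; camera adjusted p = 1.98e-06, adjusted p = 0.307 with an estimated correlation), with the signal bmp4 (-1.42 ± 0.11), the matrix proteoglycan vcana (-1.47 ± 0.13) and the repressors tbx2a (-0.92 ± 0.09) and tbx2b (-0.98 ± 0.14). Of 24 cardiac transcription factors, 9 fell and 0 rose (12 fell adjusted over the list alone; camera adjusted p = 5.14e-06, adjusted p = 0.307 with an estimated correlation). Among these, nkx2.7 went from 318 CPM at 25 hpf to 0.26 CPM at 60 dpf (-1.60 ± 0.08). The slopes of nkx2.5 (-0.15 ± 0.08), gata4 (-0.16 ± 0.12), tbx5a (-0.29 ± 0.10) and hand2 (-0.19 ± 0.07) did not pass. Of 19 embryonic RNA-binding and chromatin genes, 9 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 2.78e-05, adjusted p = 0.130 with an estimated correlation), with lin28a (-2.50 ± 0.23), sall4 (-1.26 ± 0.09) and igf2bp1 (-0.70 ± 0.09). Of 19 endocardial and valve genes, 9 fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.00668, adjusted p = 0.505 with an estimated correlation). Sarcomere genes rose in 8 and fell in 3 of 41 cases (9 and 4 adjusted over the list alone; camera adjusted p = 0.0177, adjusted p = 0.366 with an estimated correlation). Circadian and hormone genes rose in 7 and fell in 3 of 31 cases (8 and 4 adjusted over the list alone; camera adjusted p = 0.0230, adjusted p = 0.673 with an estimated correlation). Of 83 ribosomal protein genes 2 rose (2 adjusted over the list alone; camera adjusted p = 0.00214, adjusted p = 0.852 with an estimated correlation). Among markers of other cells, 3 of 4 hatching gland genes fell and 1 rose (camera adjusted p = 0.0249, adjusted p = 0.442 with an estimated correlation). Of 6 neuron markers, 3 fell (4 adjusted over the list alone; camera adjusted p = 0.0253, adjusted p = 0.348 with an estimated correlation).

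In total 3521 of 14841 genes were called in cardiomyocyte-like sums, 1683 rising and 1838 falling, and 15 lists passed camera. The core muscle genes myl7 (0.21 ± 0.08), tnnt2a (0.18 ± 0.09), ryr2b (0.06 ± 0.08) and nppa (-0.25 ± 0.15) were not called. The class came mostly from cluster 4 at 25 hpf, clusters 2 and 10 at 36 hpf, cluster 32 at 48 hpf, cluster 8 at 7 dpf and cluster 15 at 60 dpf, and later stages shared clusters. The count was 2202 without the 25 hpf library, 2234 without the 36 hpf library and 1111 without the 25 and 48 hpf libraries, when 29.1% of the calls remained. Hatching gland genes moved with these lists, with he1.1 at -3.83 ± 0.41, and so did adult globins such as hbaa1 (2.86 ± 0.61), which are uncertain.

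**Figure D2:**
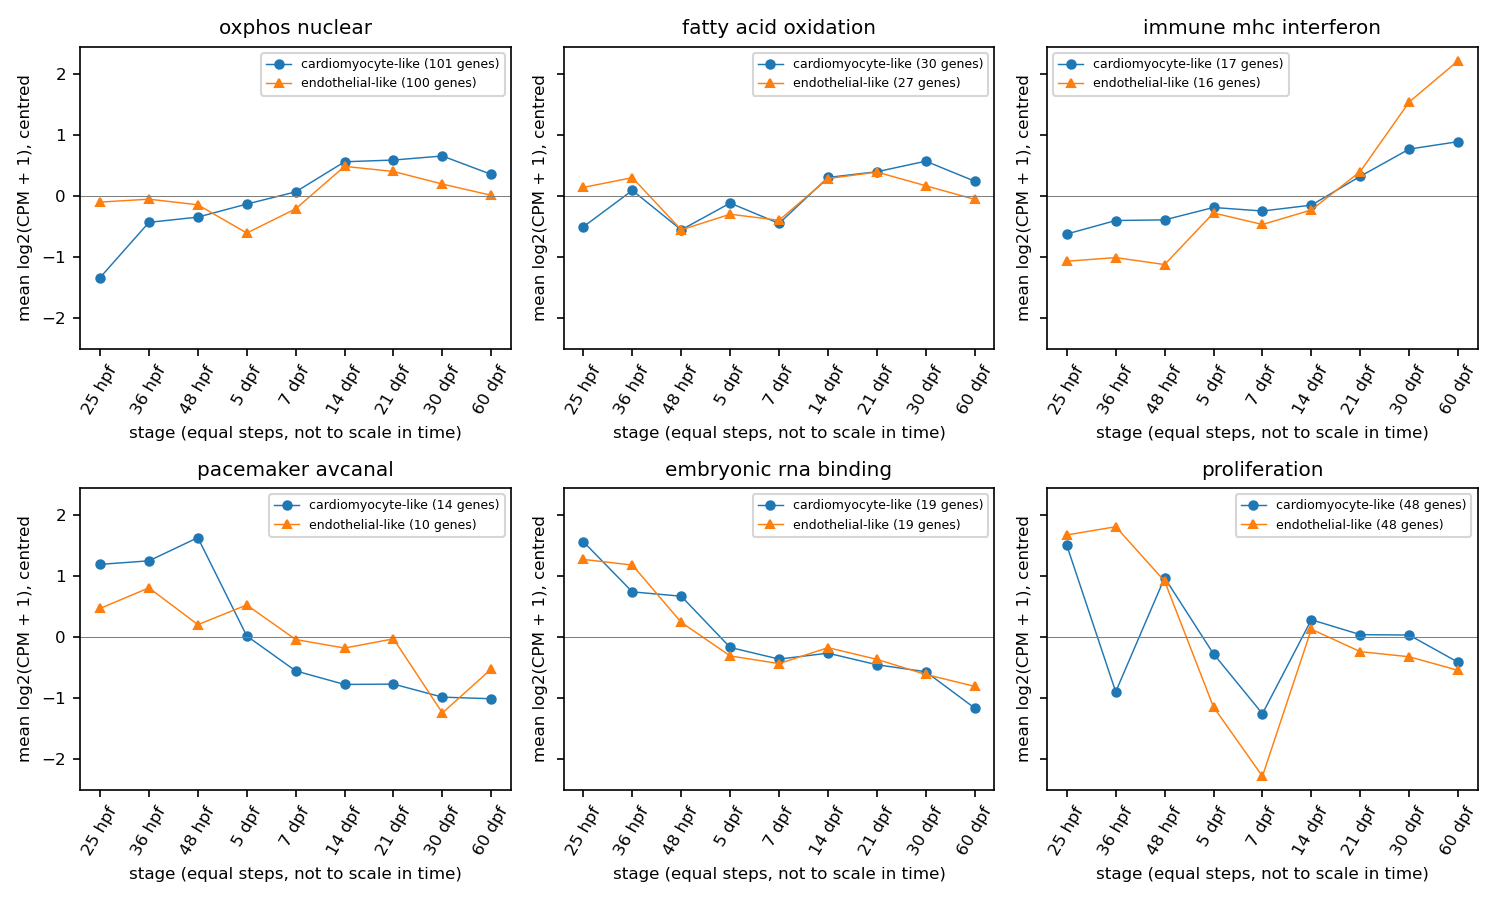
Mean log2(CPM + 1) of 6 gene lists, centred on the mean over libraries (vertical axis), by stage (horizontal axis, equal steps), for cardiomyocyte-like sums (circles) and endothelial-like sums (triangles); each point is 1 library and has no error bar. In cardiomyocyte-like sums 79 of 101 oxidative phosphorylation genes rose with age, and in endothelial-like sums 22 of 48 proliferation genes fell.

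In endothelial-like cells, cfd, which encodes complement factor D, went from 0.22 CPM at 25 hpf to 7623 CPM at 60 dpf (2.38 ± 0.21, edgeR adjusted p = 0.000157). The von Willebrand factor gene vwf, a clotting protein of vessel walls, rose by 1.11 ± 0.14 and the water channel aqp8a.1 by 1.25 ± 0.19. Also rising were the proteasome activator psme1 (1.94 ± 0.33), the growth factor binding protein igfbp6b (2.05 ± 0.38), cyp2ad2 (2.16 ± 0.61) and the keratin krt15 (1.91 ± 0.49). The gene krt15 was also among the leading genes of epicardial-like clusters 3 and 55, which had 0 cells at 25, 36 and 48 hpf. RNA of those cells was not tested as a source of its rise. With doublet calls kept, cfd was among the leading genes of a mural or smooth muscle-like cluster of 119 cells. Mural RNA was not tested as a source of the rise of cfd. The hairy-related repressors her15.1 (-2.19 ± 0.32), her15.2 (-1.96 ± 0.30) and her2 (-2.00 ± 0.29), which include targets of Notch signalling, fell, as did cabp5a (-2.91 ± 0.29), p3h2 (-1.91 ± 0.18) and dnase1l4.1 (-1.75 ± 0.51). The endothelial genes cdh5 (-0.12 ± 0.08), klf2a (0.10 ± 0.10) and nfatc1 (0.21 ± 0.11) were not called.

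Of 16 antigen presentation and interferon genes, 12 rose (the same number adjusted over the list alone; camera adjusted p = 2.92e-12, adjusted p = 0.0631 with an estimated correlation), with cd74a at 2.12 ± 0.19 and tapbp.1 at 0.85 ± 0.10. Here too cd74a is also a macrophage marker, and macrophage RNA was not tested. Of 48 proliferation genes, 22 fell and 0 rose (28 fell adjusted over the list alone; camera adjusted p = 2.09e-10, adjusted p = 0.555 with an estimated correlation), with aurka at -0.94 ± 0.13 and mki67 at -0.62 ± 0.17, both genes of dividing cells. The fall was not steady. In log2 units from the mean over libraries, the list stood at 1.81 at 36 hpf, -2.28 at 7 dpf, 0.13 at 14 dpf and -0.544 at 60 dpf. Of 19 embryonic RNA-binding and chromatin genes, 9 fell and 1 rose (13 and 1 adjusted over the list alone; camera adjusted p = 8.18e-09, adjusted p = 0.0631 with an estimated correlation). Of 32 circadian and hormone genes, 8 rose and 3 fell (13 and 4 adjusted over the list alone; camera adjusted p = 2.35e-05, adjusted p = 0.437 with an estimated correlation). Of 25 glycolysis genes, 9 rose (12 adjusted over the list alone; camera adjusted p = 2.35e-05, adjusted p = 0.514 with an estimated correlation). Oxidative phosphorylation did not pass as a list (7 of 100 rose, 1 fell, camera adjusted p = 0.677). Cardiac transcription factors fell in 7 of 21 cases (9 adjusted over the list alone; camera adjusted p = 2.35e-05, adjusted p = 0.105 with an estimated correlation), pacemaker and atrioventricular canal genes in 4 of 10 (4 adjusted over the list alone; camera adjusted p = 0.00493, adjusted p = 0.226 with an estimated correlation) and atrial genes in 2 of 10 (3 adjusted over the list alone; camera adjusted p = 0.0267, adjusted p = 0.437 with an estimated correlation). Among markers of other cells, macrophage markers rose in 2 of 3 cases (camera adjusted p = 0.00835, adjusted p = 0.226 with an estimated correlation). Neural progenitor markers fell in 3 of 8 cases (6 adjusted over the list alone; camera adjusted p = 0.000264, adjusted p = 0.147 with an estimated correlation) and neutrophil markers in 3 of 5 (4 adjusted over the list alone; camera adjusted p = 0.0239, adjusted p = 0.437 with an estimated correlation). Of 14 cardiomyocyte markers 2 rose (camera adjusted p = 0.322).

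In total 1933 of 14388 genes were called, 1058 rising and 875 falling, and 11 lists passed camera, of which 0 passed with an estimated correlation. DESeq2 called 3066 genes. The count was 992 without the 36 hpf library, 1097 without 48 hpf, 1176 without 21 dpf, 1212 without 30 dpf and 421 without both 25 and 48 hpf, when 19.5% of the calls remained. Cluster 13 held most of the class at 25 hpf, cluster 11 at 48 hpf and cluster 23 at 60 dpf. Both classes shared 372 rising genes and 391 falling genes among 13078 tested in both, where independent lists would share 88.6 and 92.1, and 36 moved in opposite directions. The same libraries gave both sums, so the overlap is not a comparison of independent samples.

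Atrial and ventricular cells differed in contractile, channel and metabolic genes. Higher in atrial cells were the troponin C gene tnnc1b (8.18 ± 0.45 log2 units, higher in 9 of 9 libraries, edgeR adjusted p = 2.59e-08), the potassium channel genes kcnj5 (7.76 ± 0.46) and kcnj19a (6.21 ± 0.58, 8 of 9 libraries), smtnl1 (7.49 ± 0.57), the Notch-modifying enzyme mfng (7.72 ± 0.50, 8 of 9 libraries), trib1 (6.96 ± 0.33, 8 of 9 libraries), fgf13a (6.52 ± 0.38) and the atrial transcription factor nr2f1a (5.98 ± 0.43). Higher in ventricular cells were the heavy chain myh7l (-6.79 ± 0.36, 9 of 9 libraries), tnni4a (-5.82 ± 0.50, 8 of 9 libraries), the Iroquois factors irx1a (-5.46 ± 0.39) and irx2a (-5.64 ± 0.34), gpr22a (-4.89 ± 0.27), tnni2b.1 (-4.80 ± 0.37), dicp1.3-4 (-7.02 ± 0.35, 8 of 9 libraries) and the repressor hey2 (-4.71 ± 0.23). The fitted value of tnni2a.4 was -6.58 ± 0.31, but it was higher in ventricular cells in 5 of 9 libraries, with 0 and 377 CPM in atrial and ventricular cells at 25 hpf and at most 0.04 CPM in either from 5 dpf on.

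**Figure D3:**
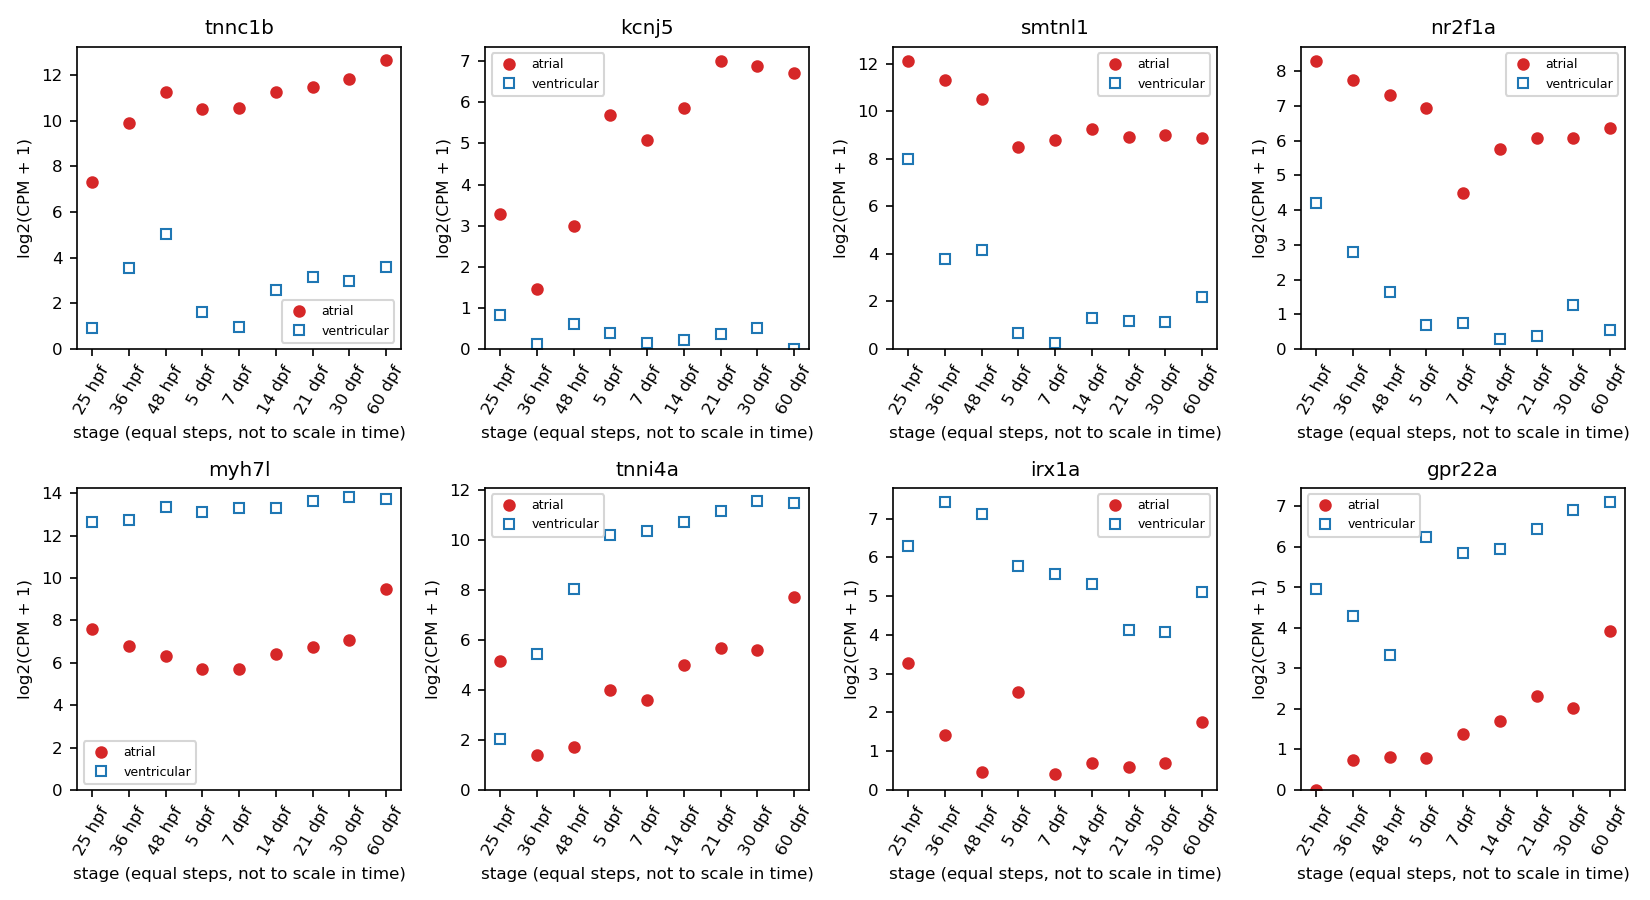
Levels as log2(CPM + 1) (vertical axis) of 8 genes in atrial (filled circles) and ventricular (open squares) sums by stage (horizontal axis, equal steps); each point is 1 sum of 1 library, without error bars. The first 4 genes were higher in atrial sums in 9 of 9 libraries, and tnni4a was higher in ventricular sums in 8 of 9.

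Genes of energy metabolism were lower in atrial cells. Of 101 nuclear oxidative phosphorylation genes, 92 were lower and 0 higher (93 and 1 adjusted over the list alone; camera adjusted p = 1.47e-39, adjusted p = 0.159 with an estimated correlation). Of 30 fatty acid oxidation genes, 24 were lower (24 adjusted over the list alone; camera adjusted p = 1.79e-16, adjusted p = 0.112 with an estimated correlation), with acsl1b at -1.99 ± 0.19 and fabp3, a fatty acid carrier, at -1.91 ± 0.35. The citric acid cycle gave 20 of 23 lower (21 adjusted over the list alone; camera adjusted p = 9.18e-12, adjusted p = 0.159 with an estimated correlation). Glycolysis gave 17 of 28 lower and 1 higher (19 and 3 adjusted over the list alone; camera adjusted p = 1.71e-10, adjusted p = 0.0184 with an estimated correlation). Pacemaker and atrioventricular canal genes were higher in 8 of 13 cases (8 adjusted over the list alone; camera adjusted p = 9.43e-12, adjusted p = 0.0184 with an estimated correlation), led by shox2 (7.29 ± 0.31), a factor of the pacemaker region. Of 12 ion channel and junction genes, 7 were higher in atrial cells (camera adjusted p = 7.18e-06, adjusted p = 0.0881 with an estimated correlation). Dissociation stress genes were higher in 17 of 38 cases (camera adjusted p = 7.18e-06, adjusted p = 0.595 with an estimated correlation), with egr1 at 1.16 ± 0.19. The atrial list had 7 of 10 members higher (7 adjusted over the list alone; camera adjusted p = 6.80e-11, adjusted p = 0.0184 with an estimated correlation). The ventricular list had 7 of 11 lower and 3 higher (7 and 3 adjusted over the list alone; camera adjusted p = 8.30e-11, adjusted p = 0.0184 with an estimated correlation). Sarcomere genes were lower in 17 and higher in 5 of 39 cases (20 and 6 adjusted over the list alone; camera adjusted p = 0.000951, adjusted p = 0.482 with an estimated correlation). Lower in atrial cells were also 11 of 13 mitochondrially encoded genes, which are uncertain (camera adjusted p = 1.58e-05, adjusted p = 0.595 with an estimated correlation), 3 of 83 ribosomal protein genes (camera adjusted p = 0.000115, adjusted p = 0.855 with an estimated correlation) and 6 of 19 vascular genes, with 1 higher (camera adjusted p = 0.00566, adjusted p = 0.218 with an estimated correlation).

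Of 14157 genes, 2885 were called, 1167 higher in atrial and 1718 higher in ventricular cells. The natriuretic peptide genes nppa (0.86 ± 0.25) and nppb (1.39 ± 0.30) were higher in atrial cells, and tnnt2a (-0.20 ± 0.11) and tnni1b (-0.23 ± 0.10) were not called. The chambers held 65 atrial and 1267 ventricular cells at 25 hpf, where 489 lay between the limits and 167 within 0.05 of a limit. At 48 hpf they held 163 and 118 cells with 211 between the limits and 80 near a limit, and at 60 dpf 285 and 640 cells with 3 between and 9 near. Sums thinned to the smallest total left 1686 genes to test and 348 calls.

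The chamber difference itself changed with age for 556 genes, 316 toward atrial and 240 toward ventricular cells. The split was less sharp early on, with 489 cells between the limits at 25 hpf, 424 at 36 hpf and 3 at 60 dpf. Cells left out for under 5 UMIs of both genes numbered 35, 4 and 323 at these stages. The effect of the split on these changes was not tested directly. With limits of 0.9 and 0.1, 86.7% of the calls were kept with the same sign, with 23 atrial cells at 25 hpf. The potassium channel gene kcnj19a was at 0 CPM in atrial cells at 25 hpf and at 147 CPM at 60 dpf, with 0.91 and 0.10 CPM in ventricular cells (1.60 ± 0.15 log2 units per doubling of age, edgeR adjusted p = 1.58e-05). The atrial sum at 25 hpf held 65 cells, or 20 with at least 20 chamber UMIs required. A level of 0 CPM in so small a sum does not establish absence. The difference also moved toward atrial cells for alpi.1 (1.64 ± 0.25), her2 (1.27 ± 0.14) and the sodium pump gene atp1a3b (1.19 ± 0.14). It did so too for kcnj5 (1.07 ± 0.20), mfng (1.08 ± 0.27) and nppa (0.35 ± 0.09). For bmp4 it moved from 521 CPM in atrial and 1171 CPM in ventricular cells at 25 hpf to 8.19 and 0.82 CPM at 60 dpf (0.78 ± 0.07). It moved toward ventricular cells for the Wnt antagonist sfrp5 (-0.83 ± 0.10), anxa2a (-0.82 ± 0.15), COLEC10 (-0.82 ± 0.12), the matrix link protein hapln1a (-0.68 ± 0.15), fabp3 (-0.51 ± 0.11) and atp2a2a (-0.57 ± 0.14). Both sfrp5 and COLEC10 were among the leading genes of unnamed cluster 26. That cluster had 199, 359 and 57 cells at 25, 36 and 48 hpf and 0 at later stages. Its RNA was not tested as a source of their change. Of 10 atrial genes, 3 moved toward atrial cells (6 adjusted over the list alone; camera adjusted p = 0.000200, adjusted p = 0.112 with an estimated correlation). Of 31 matrix genes, 7 moved toward ventricular cells and 1 toward atrial (9 and 2 adjusted over the list alone; camera adjusted p = 0.000200, adjusted p = 0.296 with an estimated correlation). Markers of other cells moved the same way as the matrix genes: epicardial markers toward ventricular cells in 1 of 7 cases (5 adjusted over the list alone; camera adjusted p = 0.000245, adjusted p = 0.194 with an estimated correlation), fibroblast markers in 2 of 14 (6 adjusted over the list alone; camera adjusted p = 0.000911, adjusted p = 0.387 with an estimated correlation) and mural markers in 2 of 12 (3 adjusted over the list alone; camera adjusted p = 0.00214, adjusted p = 0.194 with an estimated correlation). The smallest p was that of ribosomal protein genes, toward atrial cells with 0 of 83 genes called (camera adjusted p = 1.08e-10, adjusted p = 0.601 with an estimated correlation). Neural progenitor markers, in which the her4 genes are counted, moved toward atrial cells in 4 of 9 cases (camera adjusted p = 6.07e-05, adjusted p = 0.0921 with an estimated correlation). In all 15 lists passed camera in this test, and none with an estimated correlation. The others toward ventricular cells were proliferation, with 0 of 48 genes called (camera adjusted p = 0.000573), lymphatic and venous genes (0.00632), mitochondrially encoded genes (0.00632) and fatty acid oxidation (0.00904). The others toward atrial cells were ion channels and junctions (0.00632), pacemaker and atrioventricular canal genes (0.0158), cardiac transcription factors (0.0230) and thrombocyte markers (0.0402). Without the 36 hpf library 257 genes were called, 198 toward atrial and 59 toward ventricular cells. The count of genes was 340 without the 21 dpf library (212 toward atrial and 128 toward ventricular cells), 876 without a low-count filter and 50 in thinned sums.

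The adult share of hemoglobin transcripts, over all barcodes, was 0.00192% at 25 hpf (95% interval 0.000960 to 0.00344), 0.0604% at 14 dpf, 31.7% at 21 dpf, 99.86% at 30 dpf and 99.5% at 60 dpf. It rose with age (rho = 0.967, exact permutation p = 0.000165; r = 0.785, exact permutation p = 0.00599). Without the 2 libraries farthest from the median age, r was 0.689. In erythroid-like cells alone the share was 0.00161% at 25 hpf, 0.00511% at 36 hpf, 0.0237% at 48 hpf, 0.000499% at 5 dpf, 0% at 7 dpf and 0.00177% at 14 dpf. The rise from 5 to 14 dpf over all barcodes is therefore not established in red cells, which were 10 cells at 7 dpf and 20 at 14 dpf. The share there was 27.7% at 21 dpf, 99.93% at 30 dpf (8 cells) and 99.98% at 60 dpf (1 cell), and rho over all stages was 0.617 (exact permutation p = 0.0857).

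Proliferation transcripts in cardiomyocyte-like sums were 2722 CPM at 25 hpf, 1145 at 36 hpf, 534 at 7 dpf, 1545 at 14 dpf and 683 at 60 dpf. No trend passed (rho = -0.4, exact permutation p = 0.291; r = -0.578, exact permutation p = 0.0969), and r was -0.113 without the 2 libraries farthest from the median age. As a list, 8 of 48 genes rose and 6 fell (camera adjusted p = 0.972).

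**Figure D4:**
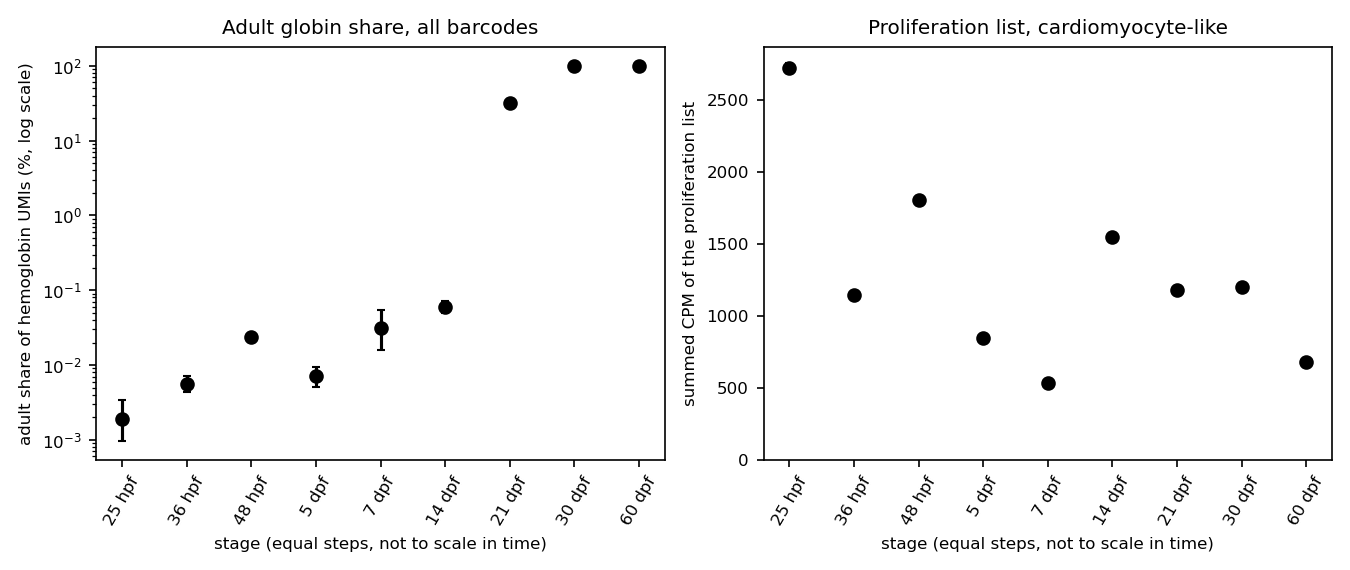
Left, adult share of hemoglobin UMIs in percent on a log axis; right, summed CPM of the proliferation list in cardiomyocyte-like sums, both by stage in equal steps. Points are single libraries with 95% counting intervals; the adult share was 0.0604% at 14 dpf and 31.7% at 21 dpf.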

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

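The tests on hatching gland and skeletal muscle transcripts were chosen after the result was seen, and the common UMI minimum was added after the data were seen. The other tests in this part had their bounds set before their values were seen.

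The chamber difference of 19 genes named by the size of their change or chosen before any value was seen differed between stages by a test of the interaction of chamber with age. Genes named only as members of a list, such as bmp4 (0.78, toward atrial cells), are not among the 19. The slopes toward atrial cells were alpi.1 1.64, kcnj19a 1.60, her2 1.27, meis2a (ENSDARG00000077840) 1.23, atp1a3b 1.19, mfng 1.085, kcnj5 1.07 and nppa 0.35. The slopes toward ventricular cells were sfrp5 -0.83, anxa2a -0.82, COLEC10 -0.82, cdkn1ca -0.755, igfbp5b -0.71, tns1b -0.68, hapln1a -0.68, txn -0.66, atp2a2a -0.57 and fabp3 -0.51. Of these, sfrp5 and COLEC10 were also leading genes of unnamed cluster 26, whose RNA was not tested as a source. For dicp1.3-4 the fitted slope was 1.25, but DESeq2 gave a dicp1.3-4 chamber by age slope of -0.848 (adjusted p = 0.654). Its levels were 0 CPM in both chambers at 25 hpf and 0.14 CPM in atrial against 121 CPM in ventricular cells at 5 dpf, so its direction is not settled. For the count of 556 genes, 1 of 40 drawn orders of the ages, the real one, gave as many and the highest other gave 320. Chance is therefore an unlikely source of this count, but 40 orders cannot exclude it. For the 2885 genes of the chamber difference, 1 of 40 flips, the real one, gave as many and the highest other gave 1013. The flips do not test the split itself. Cells were split by their own myh6 and myh7 UMIs, so genes that vary with these would differ alike in all libraries. No conclusion on chance is drawn for this count.

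In cardiomyocyte-like cells 3521 genes were called. The real order of the ages was the only 1 of 40 drawn that gave as many, and the highest other gave 1427. Chance is therefore an unlikely source of this count, but 40 orders cannot exclude it. The low UMI counts of the 25 hpf library could have made these calls. With a common UMI minimum 91.1% of them were called with the same sign, so most calls did not need the cells under this minimum. At 25 hpf it kept 386 of 1856 cells but 6444806 of 9343521 UMIs. The sum thus kept most of its counts, and the test cannot decide on other traits of this library. Without the 25 hpf library 55.9% of the calls were kept with the same sign. Without the 25 and 48 hpf libraries, the last in the numbering of the labels, 29.1% of the calls remained, and the cause of the loss was not tested. With 1 library per stage, age and differences between libraries cannot be told apart, and both stay open.

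In endothelial-like cells 1933 genes were called. The real order was the only 1 of 40 drawn that gave as many, and the highest other gave 697. Chance is again unlikely but not excluded by 40 orders. RNA set free by cardiomyocytes could have carried their trend into these sums. Of the called genes, 4.4% had a mean level under 10% of that in cardiomyocyte-like sums, against 2.87% of all tested genes, which argues against free RNA of cardiomyocytes as the whole source and leaves it open for those genes. Free RNA of other classes was not tested. Age and differences between libraries stay open here too.

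In cardiomyocyte-like cells 3 of 4 hatching gland markers (he1.1, he1.2 and ctslb) fell with age and 1 rose, while of 9 skeletal muscle markers 4 fell and 2 rose and the list missed camera (adjusted p = 0.125, adjusted p = 0.348 with an estimated correlation), and free RNA is a candidate source for the falling genes. Hatching gland UMIs per cell at 36 hpf differed 95.5-fold between the highest and lowest class, past the bound of 10 that was set against free RNA. That bound was wrong, because the highest class was the epidermal one, where 11 cells held 99.2% of the UMIs of its cluster 44 and would be the source. Without that class the range was 1.39-fold, from 3.01 to 4.17 UMIs per cell, as free RNA spread over all cells would give. For 4 falling skeletal muscle genes the median chamber difference was -2.04, with values from -6.58 to 1.80. By the bound of 2 as written, this median would count against free RNA. It passed the bound by less than the spread of the genes, a condition that the written bound did not contain. For these genes as a set, free RNA and expression in ventricular cells therefore cannot be told apart.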

How the results depend on the processing

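Among these values, the common UMI minimum, which held every library to the highest of the lowest UMI counts, was added after the data were seen. Of the counts and correlations under alternatives, 117 stayed within 1.5 times of the first count or on the same side of the threshold, 21 counts moved further and 1 correlation lost its call. The cardiomyocyte trend called 1111 genes without the 25 and 48 hpf libraries, where 7 libraries were tested. With 1 library left out it called between 2202 and 3947, with 2202 without 25 hpf and 2234 without 36 hpf. The endothelial trend called 3066 genes with DESeq2, and 421 without the 25 and 48 hpf libraries. With 1 library left out it called between 992 and 2251, with 992 without 36 hpf, 1097 without 48 hpf, 1176 without 21 dpf and 1212 without 30 dpf. The chamber difference called 348 genes in thinned sums, where only 1686 genes passed the count filter. The chamber by age test called 876 genes without a low-count filter, 50 in thinned sums with the same 1686 genes, and between 257 and 675 with 1 library left out, with 257 without 36 hpf (198 toward atrial and 59 toward ventricular cells) and 340 without 21 dpf. With an estimated correlation between genes, 1 cardiomyocyte list (antigen presentation and interferon) and 0 endothelial lists passed camera, against 15 and 11 with the preset value. Between 0 and 4 class shares passed with 1 library left out, with 0 without 25 hpf, 36 hpf, 48 hpf or 14 dpf, and 0 passed when cells were clustered within each library. The globin correlation was 0.617 in erythroid-like cells alone (exact permutation p = 0.0857), where the shares at 5, 7 and 14 dpf lay below that at 36 hpf. The cause was not tested for the other changes. The stricter filter and the common minimum left 15 and 5 atrial cells at 25 hpf, so that library left the chamber tests there.

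For the named genes, 2667 values kept their direction and their side of the threshold, 157 kept the direction and lost the call, 43 gained a call and 105 changed sign. The only gene with a sign change that was called was dicp1.3-4 in the chamber by age test.

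In the cardiomyocyte trend, values with the other sign were myh6 0.003 with DESeq2 and myh6 0.003 with RLE size factors. Others were myh6 0.006 with no low-count filter and myh6 0.005 with thinned sums. There were also myh6 0.009 with stage rank and myh6 0.116 with the stricter cell filter. There were also myh6 0.03 with the common UMI minimum and tnni1b -0.05, mki67 0.246, top2a 0.298 without 25 and 48 hpf. With 1 library left out, the ranges were myh6 cardiomyocyte trend -0.131 to 0.072, tnni1b cardiomyocyte trend -0.046 to 0.086. The cause was not tested.

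In the endothelial trend, values with the other sign were myh6 -0.1, nppb -0.038, tnni1b -0.026, ryr2b -0.176 with doublets kept and nppb endothelial trend -0.184, tnni1b -0.012, ryr2b -0.036, nr2f1a 0.041 without 25 and 48 hpf. Others were tnnt2a 0.005, gata4 0.015 with thinned sums and tnnt2a 0.003 with stage rank. There were also tnnt2a 0.048 with clustering within each library and ryr2b -0.004 with DESeq2. There were also ryr2b -0.003 with RLE size factors and ryr2b -0.003 with the stricter cell filter. With 1 library left out, the ranges were myh6 endothelial trend -0.062 to 0.18, nppa endothelial trend -0.269 to 0.18, nppb endothelial trend -0.087 to 0.302, tnnt2a endothelial trend -0.091 to 0.044, tnni1b endothelial trend -0.022 to 0.182. Further ranges were ryr2b endothelial trend -0.052 to 0.107, gata4 endothelial trend -0.109 to 0.05, fabp3 endothelial trend -0.234 to 0.145, cox4i1 endothelial trend -0.102 to 0.005, nr2f1a endothelial trend -0.098 to 0.12. The cause was not tested.

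In the chamber difference, values with the other sign were tnnt2a 0.053, tnni1b 0.001 with thinned sums and mki67 0.017 with RLE size factors. Others were mki67 0.211 with doublets kept and mki67 0.102 with the common UMI minimum. There were also klf2a -0.01 with no low-count filter. With 1 library left out, the ranges were mki67 chamber difference -0.213 to 0.208, klf2a chamber difference -0.273 to 0.33, nfatc1 chamber difference -0.053 to 0.293. The cause was not tested.

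In the chamber by age test, values with the other sign were dicp1.3-4 chamber by age -0.848, tnni4a -0.233 with DESeq2 and myl7 0.018, nppb 0.255, ryr2b 0.071, cdh5 0.202 without 25 and 48 hpf. Others were myl7 0.001, nppb 0.086, ryr2b 0.076, hand2 -0.098, cdh5 0.037 with the stricter cell filter and myl7 0.015, nppb 0.122, tnnt2a 0.036 with limits of 0.9 and 0.1. There were also nppb 0.08, ryr2b 0.044, hand2 -0.038, cdh5 0.067 with the common UMI minimum and tnni1b -0.029, tnni4a chamber by age -0.109, nr2f1a -0.132 with thinned sums. There were also cdh5 0.012 with doublets kept and cdh5 0.03 with at least 20 chamber UMIs. With 1 library left out, the ranges were nppb chamber by age -0.353 to 0.085, tnnt2a chamber by age -0.052 to 0.005, tnni4a chamber by age -0.172 to 0.371, ryr2b chamber by age -0.188 to 0.043, hand2 chamber by age -0.048 to 0.146. Further ranges were mki67 chamber by age -0.242 to 0.042, cox4i1 chamber by age -0.048 to 0.03, nfatc1 chamber by age -0.232 to 0.047, cdh5 chamber by age -0.238 to 0.067. The cause was not tested.

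No paired analysis was possible because each stage has 1 library and no number is shared by the libraries beyond the chamber sums, which were compared within libraries.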

Other observations

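The clusters in this part were chosen after their leading genes were seen. Cluster 60 held 44 cells, 90.9% of them from 5 dpf, and its leading genes included shox2, isl1, bmp5, fgf13a, id4 and chrm2a, of which shox2 and isl1 are known from the pacemaker region. Cluster 30 held 542 cells, 501 of them from 5 dpf, with myb, a gene of blood progenitors, among its leading genes. Cluster 22 (735 cells, 609 at 36 hpf) and cluster 25 (637 cells, 634 at 25 hpf) carried the distal-less genes dlx2a and dlx3b, which are known from the pharyngeal arches. These clusters met fewer than 3 markers of a class and stayed unnamed.

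The Notch target her4.1, chosen after its values were seen, was at 12.3 CPM in cardiomyocyte-like cells at 36 hpf, 1021 CPM at 21 dpf and 39.5 CPM at 60 dpf. Its slope was 0.65 ± 0.38 (edgeR adjusted p = 0.233).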
